A study of Homo sapiens and Mus musculus with 22 samples.

How the data were processed

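RNA was sequenced, per the labels' protocols, from small cell lung cancer lines after exome capture of libraries made from 250 ng of RNA, on a NextSeq 500. The deposited tables hold whole-number read counts per gene, 1 table for H69 and H69M with its PD-L1 fractions, 1 for the H69EZ fractions and 1 for the mouse lines. STAR 2.6.1 is named per the submitters' processing notes, with genome builds hg19 and mm10. The program that counted reads, its gene annotation and its use of strand are not given in the sources used here, so genes that overlap or lie antisense to another are uncertain.

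All 22 libraries were used, in the 8 groups of the labels. The mouse columns carry no replicate numbers of the labels and were assigned by group only, with the columns named RPPM taken as RPP-A. The tables list 25435, 20113 and 24047 genes, of which 24215 and 19194 symbols of the human tables matched the reference names. Since the reference is of another build, no coordinates are given.

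Each table was fitted on its own in R 4.3.3 with edgeR 4.0.16, by the quasi-likelihood F-test with TMM normalisation and 1 coefficient per group, two-sided. Genes passed filterByExpr with a minimum count of 10, which left 15445, 14819 and 14032 genes. All groups of a table shared the estimate of spread. The common biological coefficient of variation was 0.0540, 0.0450 and 0.157. Adjusted p-values are Benjamini-Hochberg values over the genes of a comparison, with a threshold of 0.05, and the SE of a log2 fold change was taken as its size over the square root of F. In the H69EZ table, with 2 residual degrees of freedom, the spread was pooled wholly across genes. The difference between the PD-L1 sort and H69M minus H69 was a contrast in the same fit.

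Lists were 25 fixed sets of genes: MHC class I and class II presentation, interferon-stimulated genes, nucleic acid sensing, NF-kB targets and cytokines, checkpoint and NK cell ligands, neuroendocrine and non-neuroendocrine SCLC signatures, SCLC lineage and MYC factors, mesenchymal and epithelial markers, YAP and TAZ targets, Notch pathway, TGF-beta and activin targets, integrins and focal adhesion, synaptic and secretory granule genes, PRC2 and H3K27 demethylases, receptor tyrosine kinases and ligands, proliferation, cancer testis antigens, leukocyte, fibroblast and stromal, and endothelial markers, sorting stress and immediate early genes, and mitochondrially encoded genes. Those with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over lists, and again with the correlation estimated and with fry. A rise or fall of a member means an adjusted p under 0.05 over all genes.

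The comparisons, tests, lists, the rule for named genes and all alternatives not named below as added were fixed before the data were examined. Named genes were a fixed panel of MHC class I, lineage and sort genes, the 4 largest rises and 4 largest falls by fitted fold of each comparison among genes expressed at or above the median with groups that do not overlap, and leading members of lists. Some genes that this rule names are not reported here. Genes of the difference test, of the shared changes and those singled out for EHK_RPP4 were named after their values were seen where this rule does not cover them. Overlaps of calls were set against the product of the shares of calls, and mouse genes were matched to human genes by symbol.

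Total counts ran from 10817795 to 52458228 per library. Ratios for genes with 1 to 3 counts in a group carry exact binomial 95% intervals. These intervals and the floor of 3 counts over a group cover counting error only. On simulated counts with 200 genes changed by known folds, 2-fold changes were called for 95.5% of genes in H69M minus H69 (15148 genes tested), 98.5% in the PD-L1 sort (15146), 100% in the HLA sort (14654), 92.5% in RPP-A minus RPP (13816), 100% in PD-L1 low minus H69 (15152) and 86.6% in the difference (15163). For 1.5-fold changes these shares were 89.6%, 77.6%, 97.0%, 44.8%, 88.1% and 83.6%, with 10, 10, 5, 5, 15 and 12 unchanged genes called. The simulated changes were few and balanced between rises and falls, whereas 71.4% to 81.3% of tested genes were called in the real data. These rates therefore hold for the simulated setting only and do not show how TMM scaling fares on the real counts.

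Alternatives were the replicate number as a block, no filter or a minimum count of 100, DESeq2 1.42.0 size factors, the DESeq2 test, limma-voom, only the groups compared, a 2-fold minimum and each library left out in turn. Added after the data were seen were library totals without TMM, the H69EZ table without mitochondrially encoded genes, the mouse table without Rn45s, RPPM1 and RPPM2 summed, EHK_RPP4 and RPPM3 left out, for the amino acid response list of the closing section, EHK_RPP4 alone left out, and the MHC class I list of the HLA sort without 6 class I heavy chain genes and B2M. Library totals alone moved the median log2 fold change of all genes by -0.14 in the PD-L1 sort, -0.15 in the HLA sort, -0.37 in RPP-A minus RPP and -0.18 in the difference, so changes are relative to the TMM scale. No library was left out of the reported values.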

Results

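Expression was measured by RNA sequencing in small cell lung cancer (SCLC) cells that differ in MHC class I, the surface complex that presents peptides to cytotoxic T cells. NCI-H69 (H69) is a human SCLC line labelled low or negative for MHC class I. H69M is a derivative of H69 labelled MHC class I high. It was also sequenced after sorting into fractions high and low for PD-L1, the immune checkpoint ligand encoded by CD274. The PD-L1 low fraction is labelled MHC class I low and the PD-L1 high fraction MHC class I high. H69EZ was derived from H69 by a passing exposure of 6 days to an EZH2 inhibitor, followed by culture without the drug and selection of adherent cells. Its libraries come from fractions sorted low and high for surface HLA class I. RPP is a mouse SCLC line labelled MHC class I low, and RPP-A is the MHC class I high line obtained from it by adherent growth. The question in each comparison was how cells with high MHC class I differ in expression from the related cells with low MHC class I.

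The 22 libraries fell into 8 groups in 3 count tables. Each table was analysed on its own, since counts of different tables were made and normalised separately. Total counts per library were 12814594 to 26834561 in H69, 19905007 to 25806038 in H69M, 13104998 to 21499865 in its PD-L1 low fraction and 14752176 to 21533233 in its PD-L1 high fraction (n = 3 each). They were 40758798 and 48192289 in the HLA low and 40568796 and 52458228 in the HLA high fraction of H69EZ (n = 2 each), 10817795 to 12826799 in RPP and 16693491 to 19973785 in RPP-A (n = 3 each). Levels below are means ± SD of CPM, counts scaled to a common library size after TMM normalisation, and log2 fold changes are given ± SE. A fold against a group without a count is a lower bound, taken against 3 counts over that group, and list medians are also given with such genes at their bounds where that changes them. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. HLA-B and HLA-C, like H2-K1 and H2-D1 in the mouse, are near relatives that can share reads, and the sources used here do not say how such reads were counted, so their separate values are uncertain. Of the mouse libraries, the RPP-A columns RPPM1 and RPPM2 differed from each other less than any other pair of replicates (chi-square per degree of freedom 1.35, against 2.28 to 39.3 for other pairs). This measure also grows with depth, which differs between tables. The RPP column EHK_RPP4 and the RPP-A column RPPM3 each stood apart from their group, with chi-square per degree of freedom of 29.7 to 39.3 against the other libraries of the group.

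H69M was compared with its parent H69. Most genes of the MHC class I pathway, 16 of 22, were higher in H69M, and 3 were lower. B2M, the light chain of the complex, was at 449.7 ± 22.0 against 258 ± 3.25 CPM, a log2 fold change of 0.80 ± 0.05 (n = 3 each, adjusted p = 2.35e-11). HLA-C rose by 2.07 ± 0.06 and HLA-B by 5.41 ± 0.19. The peptide transporter genes TAP1 and TAP2 rose from 0.116 ± 0.113 to 43.3 ± 1.73 CPM and from 0.757 ± 0.210 to 29.1 ± 1.03 CPM. The immunoproteasome gene PSMB8 rose by 5.64 ± 0.16, and PSMB9, without a count in H69, was at least 193-fold higher in H69M. NLRC5, a transactivator of MHC class I genes, rose by 4.26 ± 0.24 and CD274 by 5.57 ± 0.33.

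Non-neuroendocrine and mesenchymal genes were far higher in H69M than in H69. YAP1, the coactivator of the Hippo pathway, had no count in H69 and 46.6 ± 5.24 CPM in H69M, at least 999.8-fold higher. The same held for MME, at least 1278-fold higher, and for CAV2, at least 710.2-fold higher. VIM, the mesenchymal intermediate filament, was at 459 ± 7.99 against 0.0898 ± 0.0947 CPM. The receptor tyrosine kinase AXL had 1 count in H69 and was higher at a ratio of 4461-fold, with a 95% counting interval of 800.3 to 176240. REST, a repressor of neuronal genes, also had 1 count there and was higher at a ratio of 635-fold, with a 95% counting interval of 114 to 25135. Of COL6A2, with 3 counts in H69, the ratio was 6194-fold, with a 95% counting interval of 2119 to 30039.6. In the other direction, ADCY1 fell from 237 ± 12 to 0.651 ± 0.156 CPM. NEAT1 changed by -4.62 ± 0.31, OLFM1 by -4.03 ± 0.08 and ZNF704 by -3.24 ± 0.07. NEAT1 varied between the H69 libraries, at 253 ± 132 CPM.

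Neuroendocrine genes did not fall together in H69M. CHGA, a secretory granule protein, was at 307 ± 9.80 against 248 ± 7.10 CPM, slightly higher in H69M (log2 fold change 0.31 ± 0.05). INSM1 was at 1678 ± 1.5 against 1627 ± 44.9 CPM and did not pass the test (log2 fold change 0.04 ± 0.05, adjusted p = 0.390). SYP changed by -0.20 ± 0.07 (adjusted p = 0.0140), a call lost without H69 replicate 3 (adjusted p = 0.0940) or without H69M replicate 3 (adjusted p = 0.0853). EZH2, the catalytic subunit of the PRC2 complex, fell from 302 ± 7.62 to 239 ± 10.9 CPM (adjusted p = 1.95e-06).

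Among the fixed gene lists in H69M against H69, 27 of 31 rose and 2 fell of the mesenchymal markers, 24 of 25 rose and 1 fell of the non-neuroendocrine SCLC signature and 18 of 21 rose and 1 fell of the YAP and TAZ targets. Their median log2 fold changes were 4.08, or 3.93 with such genes at their bounds, 5.2 and 4.99. The camera adjusted p were 8.75e-37, 3.62e-29 and 7.84e-26, and all stayed under 0.05 with an estimated correlation. So did the receptor tyrosine kinases and ligands (23 higher, 6 lower and 0 neither; adjusted p = 2.18e-12) and the TGF-beta and activin targets (12 higher, 7 lower and 1 neither; adjusted p = 0.00262). CDH2 (3.22 ± 0.06), COL6A1 (9.66 ± 0.19), the ephrin receptor EPHA2 (5.67 ± 0.12) and AMOTL2 (6.38 ± 0.15) were among the members that rose. EGFR, with no count in H69, was at least 450.3-fold higher.

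Immune lists rose in H69M with camera at the preset correlation and with fry, but were not called by camera with an estimated correlation. In the MHC class I list 16 of 22 rose and 3 fell (adjusted p = 4.82e-11, and adjusted p = 0.0737 with an estimated correlation). Of the interferon-stimulated genes 36 of 43 rose and 5 fell, among them PARP14 (5.07 ± 0.16) and SAMD9L (7.29 ± 0.28), with an adjusted p of 1.77e-11, or adjusted p = 0.138 with an estimated correlation. Of the NF-kB targets and cytokines 17 of 21 rose and 2 fell, with CCL2 up by 5.48 ± 0.11 and ICAM1 by 5.61 ± 0.13 (adjusted p = 4.56e-06, and adjusted p = 0.0655 with an estimated correlation). The nucleic acid sensing list had 9 higher, 4 lower and 2 neither, with a median of 0.75, or 0.35 with such genes at their bounds (adjusted p = 0.00710, and adjusted p = 0.0921 with an estimated correlation). TMEM173, which encodes STING, rose by 3.68 ± 0.14. The checkpoint and NK cell ligands had 11 higher, 4 lower and 4 neither (adjusted p = 0.00639, and adjusted p = 0.10 with an estimated correlation). The integrin and focal adhesion genes had 23 higher, 5 lower and 2 neither (adjusted p = 3.97e-10, and adjusted p = 0.0921 with an estimated correlation), and LAMA3 was among those that fell (log2 fold change -2.27 ± 0.06). The lineage and MYC factors had 8 higher, 5 lower and 4 neither (adjusted p = 0.0463, and adjusted p = 0.174 with an estimated correlation), where REST and YAP1 were among those up and NKX2-1 rose by 2.00 ± 0.06. Fibroblast and stromal markers, of which 4 are also in the mesenchymal list, moved with these groups: 12 of 14 rose and 1 fell, with COL3A1 up by 7.86 ± 0.19 (9.16 without H69 replicate 2) and FBLN1 down (log2 fold change -2.56 ± 0.07). Their adjusted p was 8.57e-09, or adjusted p = 0.0655 with an estimated correlation.

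The remaining lists were not called in H69M against H69. The neuroendocrine SCLC signature had 7 higher, 9 lower and 9 neither (median -0.02, while camera pointed up, adjusted p = 0.925), and the synaptic and secretory granule genes had 9 higher, 15 lower and 2 neither (adjusted p = 0.210). The epithelial markers had 7 higher, 12 lower and 4 neither, the Notch pathway 11 higher, 10 lower and 1 neither, the proliferation genes 12 higher, 7 lower and 7 neither and the sorting stress and immediate early genes 6 higher, 8 lower and 11 neither. The PRC2 and H3K27 demethylase genes had 4 higher, 6 lower and 3 neither, with a median of 0.04 against a mean of -0.04. The cancer testis antigens had 3 higher, 3 lower and 2 neither, with a median of 0.40, or -0.08 with such genes at their bounds and a mean of 1.63. Endothelial markers had 5 higher, 2 lower and 3 neither, with ENG up by 2.55 ± 0.16 and VWF down (log2 fold change -5.50 ± 0.37). Of 4 measured leukocyte markers 2 were higher and 1, PTPRC, was lower (-3.69 ± 0.45, and -4.82 without H69M replicate 1), and of 4 measured MHC class II genes 2 were higher and 1 lower, too few for a set test. Adjusted over the list alone, every list in this comparison gave the same counts as over all genes. Over all genes, 11196 of 15445 tested differed between H69M and H69, 5540 higher and 5656 lower, and 3669 of them differed at least 2-fold. In 11262 genes the 3 values of one group all lay above the 3 of the other, where chance gives 10% of genes.

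**Figure D1:**
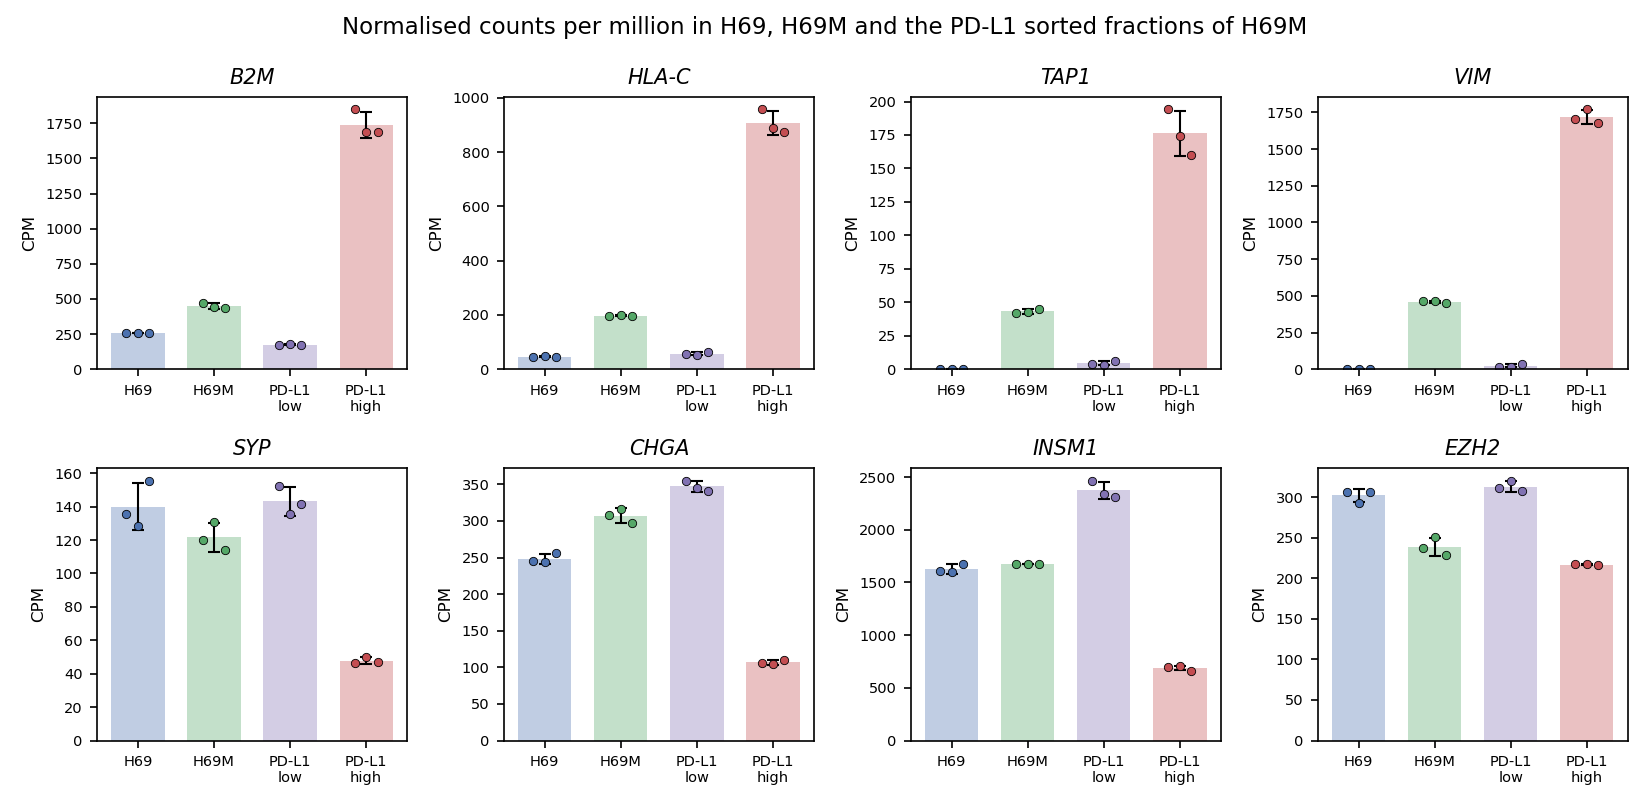
Normalised CPM (vertical axis, linear, from 0) of 8 genes in H69, H69M and the PD-L1 low and PD-L1 high fractions of H69M. Bars are means, error bars SD and points the 3 libraries of each group. B2M, HLA-C, TAP1 and VIM are highest in the PD-L1 high fraction, and SYP, CHGA and INSM1 are lowest there, at 47.8 ± 1.87, 107 ± 2.90 and 688 ± 22.3 CPM.

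Within H69M, the PD-L1 high fraction was compared with the PD-L1 low fraction. CD274 itself, at 13.3 ± 0.424 against 0.265 ± 0.152 CPM, checks the sort and is no finding. The MHC class I genes were higher in the PD-L1 high fraction without exception among the 22 measured. B2M was at 1741 ± 93.1 against 174 ± 4.23 CPM (log2 fold change 3.32 ± 0.06, n = 3 each, adjusted p = 1.90e-20), and HLA-C rose by 3.99 ± 0.06 and HLA-B by 6.38 ± 0.16. TAP1 rose by 5.34 ± 0.13, TAP2 by 3.85 ± 0.08, PSMB8 by 3.47 ± 0.08, PSMB9 by 5.41 ± 0.12 and NLRC5 by 2.83 ± 0.11.

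Neuroendocrine genes were lower in the PD-L1 high fraction. INSM1, a transcription factor of neuroendocrine cells, was at 688 ± 22.3 against 2374 ± 81.2 CPM, a log2 fold change of -1.79 ± 0.05 (n = 3 each, adjusted p = 7.61e-18). CHGA changed by -1.70 ± 0.05 and SYP by -1.58 ± 0.07, and EZH2 by -0.53 ± 0.05. All 25 genes of the neuroendocrine SCLC signature fell (median -1.58, camera adjusted p = 1.69e-15), as did all 26 measured synaptic and secretory granule genes (median -1.49, adjusted p = 7.61e-14). NCAM1, which encodes CD56, changed by -1.91 ± 0.05 and the neuropeptide gene GRP by -2.75 ± 0.08. Both lists held with an estimated correlation. Among lineage and MYC factors, 12 of 17 fell, among them MYCN (-1.76 ± 0.05), while 5, including YAP1 (6.13 ± 0.12) and REST (5.91 ± 0.14), rose (adjusted p = 0.0153, and adjusted p = 0.0613 with an estimated correlation). Of the epithelial markers 19 of 23 fell, ELF3 among them (-2.53 ± 0.06), and 4 rose, including KRT8 (2.06 ± 0.06), KRT18 (2.53 ± 0.07) and CDH3 (3.79 ± 0.09). That list had an adjusted p of 1.73e-04, or adjusted p = 0.0733 with an estimated correlation.

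Mesenchymal, adhesion and inflammatory genes were higher in the PD-L1 high fraction. VIM was at 1719 ± 45.5 against 23.7 ± 8.88 CPM, AXL rose by 7.14 ± 0.17 and large rises were those of ACTA2 (8.55 ± 0.28), IGFBP3 (8.42 ± 0.19), IFI44L (8.42 ± 0.27) and MSN (8.28 ± 0.17). Without PD-L1 low replicate 3 the log2 fold changes were 7.85 for AXL, 10.36 for ACTA2, 9.57 for IGFBP3, 11.40 for IFI44L and 9.14 for MSN. Of the mesenchymal markers 28 of 31 rose and 0 fell, of the non-neuroendocrine signature 24 of 25 rose and 0 fell, of the YAP and TAZ targets 19 of 21 rose and 2 fell and of the integrin and focal adhesion genes 29 of 30 rose and 0 fell. Their medians were 4.94, 5.80, 5.68 and 2.42. Of the interferon-stimulated genes 43 of 43 rose and 0 fell (median 4.96), of the NF-kB targets and cytokines 18 of 21 rose and 2 fell, of the nucleic acid sensing genes 13 of 15 rose and 1 fell, of the TGF-beta and activin targets 18 of 20 rose and 2 fell and of the receptor tyrosine kinases and ligands 21 of 29 rose and 6 fell. CCL2 rose by 6.37 ± 0.09, TMEM173 by 4.62 ± 0.10 and PDGFRB by 6.27 ± 0.13. Fibroblast and stromal markers moved with them (11 of 14 rose and 1 fell, median 5.11). For the MHC class I list and these lists the camera adjusted p was at most 2.64e-05, and at most 0.0268 with an estimated correlation. The checkpoint and NK cell ligands had 15 higher, 3 lower and 1 neither (adjusted p = 1.50e-06, and adjusted p = 0.0537 with an estimated correlation), and IDO1 rose by 6.11 ± 0.16. That list holds CD274, so its result was in part fixed by the sort. Of the cancer testis antigens 7 of 8 rose and 0 fell (adjusted p = 0.0195, and adjusted p = 0.137 with an estimated correlation), among them MAGEB2 (6.19 ± 0.14) and PRAME (0.41 ± 0.05).

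Large falls in the PD-L1 high fraction were those of H19 (-4.50 ± 0.15), RAB39B (-3.61 ± 0.08), DDIT4 (-3.60 ± 0.09) and INHBE (-3.55 ± 0.09). These genes stood out in the PD-L1 low fraction. H19 was at 248 CPM there, 10.9 in the PD-L1 high fraction, 20.6 in unsorted H69M and 10.9 in H69. In the same order RAB39B was at 83.3, 6.81, 14.3 and 10.8 CPM. DDIT4 was at 1014, 83.5, 136 and 113 CPM, and INHBE at 153, 12.9, 13.0 and 30.0 CPM. The sorting stress and immediate early genes had 14 higher, 9 lower and 2 neither and were not called (adjusted p = 0.886), with ATF3 (-3.48 ± 0.07) and DDIT3 (-1.87 ± 0.07) among those that fell. The Notch pathway had 5 higher, 15 lower and 2 neither, the PRC2 and H3K27 demethylase genes 3 higher, 6 lower and 4 neither, the proliferation genes 10 higher, 11 lower and 5 neither and the endothelial markers 7 higher, 3 lower and 0 neither, none of them called. Of 4 measured leukocyte markers 3 rose, with CD68 at 6.36 ± 0.831 against 0.410 ± 0.117 CPM, and of 4 MHC class II genes 2 rose and 1 fell. Adjusted over the list alone, counts changed in 3 lists, by 1 gene each: 16 checkpoint and NK cell ligands rose, and 1 non-neuroendocrine signature gene and 1 integrin and focal adhesion gene fell. Over all genes, 12100 of 15445 differed between the fractions, 6021 higher and 6079 lower in the PD-L1 high cells, 5144 of them at least 2-fold. The 3 values of the groups were apart in 12372 genes, where chance gives 10%.

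The PD-L1 low fraction of H69M was next set against H69, since both are labelled MHC class I low. INSM1 was at 2374 ± 81.2 against 1627 ± 44.9 CPM (log2 fold change 0.54 ± 0.05, n = 3 each, adjusted p = 1.66e-09), and CHGA rose by 0.48 ± 0.05. B2M was lower in the PD-L1 low fraction (-0.57 ± 0.05), whereas TAP1 rose by 4.89 ± 0.41 (5.65 without H69 replicate 2), TAP2 by 3.45 ± 0.16 and NLRC5 by 3.78 ± 0.27. EDNRA and PRRX1, without counts in H69, were at least 137-fold and at least 99.8-fold higher, and YAP1 was at least 56.9-fold higher at 2.75 ± 0.519 CPM. These levels were 4.18%, 2.06% and 1.45% of those in the PD-L1 high fraction. The mesenchymal markers AXL and COL6A2 were at 0.807% and 0.983% of theirs. For these genes, PD-L1 high cells carried over into the PD-L1 low gate stay open as a source, as examined in the closing sections. SERPINB6, with 2 counts in H69, was higher at a ratio of 617-fold, with a 95% counting interval of 170.4 to 5100.5. ADCY1 (-6.46 ± 0.10), FHOD3 (-5.69 ± 0.09), GSTP1 (-5.60 ± 0.10) and BACE2 (-4.66 ± 0.14) were lower. SYP and EZH2 did not pass the test (0.04 ± 0.07 and 0.05 ± 0.05). CD274 was at 0.265 ± 0.152 against 0.0781 ± 0.0366 CPM (adjusted p = 0.0420). That call was lost without H69 replicate 1 (adjusted p = 0.155) or 3 (0.0627) and without PD-L1 low replicate 1 (0.0612) or 3 (0.166). Among the gene lists in this comparison, the mesenchymal markers (23 higher, 6 lower and 2 neither, adjusted p = 5.27e-07, and adjusted p = 0.535 with an estimated correlation) and the receptor tyrosine kinases and ligands (21 higher, 6 lower and 2 neither, adjusted p = 0.00332, and adjusted p = 0.366 with an estimated correlation) were higher in the PD-L1 low fraction. The neuroendocrine SCLC signature was too (19 higher, 4 lower and 2 neither, adjusted p = 0.0294, and adjusted p = 0.675 with an estimated correlation), as were the lineage and MYC factors (11 higher, 5 lower and 1 neither, adjusted p = 0.0304, and adjusted p = 0.366 with an estimated correlation). The Notch pathway (12 higher, 6 lower and 4 neither, adjusted p = 0.0348, and adjusted p = 0.535 with an estimated correlation) and the fibroblast and stromal markers (11 higher, 2 lower and 1 neither, adjusted p = 0.0348, and adjusted p = 0.756 with an estimated correlation) completed the called lists. The MHC class I list had 11 higher, 8 lower and 3 neither and was not called (adjusted p = 0.773). Median, mean and test differed in sign for the integrin and focal adhesion genes (median 0.00, or -0.19 with such genes at their bounds, mean 0.29, test down), the synaptic and secretory granule genes (median -0.02, mean 0.17, test up), the cancer testis antigens (median -0.16, or -0.31 with such genes at their bounds, mean 0.92, test down) and the endothelial markers (median 1.67, or -0.18 with such genes at their bounds, mean 0.86, test down). Adjusted over the list alone, 8 NF-kB targets and cytokines, 13 Notch pathway genes and 22 receptor tyrosine kinases and ligands rose, and no other count changed. In all, 11723 of 15445 genes differed, 6023 higher and 5700 lower in the PD-L1 low fraction, 3933 of them at least 2-fold.

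The change across the PD-L1 sort was tested against the change from H69 to H69M, as the difference of the 2 log2 fold changes, with no library shared between them. For the neuroendocrine genes the difference was -2.01 ± 0.07 for CHGA, -1.83 ± 0.07 for INSM1 and -1.38 ± 0.10 for SYP (adjusted p at most 1.72e-10). The neuroendocrine SCLC signature (camera adjusted p = 9.93e-16), the synaptic and secretory granule genes (3.46e-10) and the lineage and MYC factors (4.00e-06) were more negative across the sort, and all 3 held with an estimated correlation. B2M (2.52 ± 0.07) and HLA-C (1.92 ± 0.08) rose more across the sort, while TAP1 (-2.86 ± 0.50, and -3.63 without H69 replicate 2), TAP2 (-1.33 ± 0.19), PSMB8 (-2.18 ± 0.25) and NLRC5 (-1.43 ± 0.34) had the larger fold from H69 to H69M. TAP1, TAP2 and NLRC5 started lower in H69 than in the PD-L1 low fraction, so the larger fold does not mean a higher level in H69M. The smaller rise of B2M and HLA-C in H69M may come from a mixture of the 2 fractions in unsorted H69M, examined below for the MHC class I list. The MHC class I list was more positive across the sort (adjusted p = 2.47e-05, and adjusted p = 0.171 with an estimated correlation), as were the integrin and focal adhesion genes (adjusted p = 1.90e-08, and adjusted p = 0.166 with an estimated correlation), the interferon-stimulated genes (adjusted p = 6.37e-04, and adjusted p = 0.536 with an estimated correlation) and the TGF-beta and activin targets (adjusted p = 0.0422, and adjusted p = 0.235 with an estimated correlation). The epithelial markers were more negative (adjusted p = 3.12e-04, and adjusted p = 0.214 with an estimated correlation). Among the largest differences were those of NEAT1, which changed by -4.62 in H69M and rose by 4.06 across the sort, and of ABAT, which rose by 6.11 in H69M and changed by -1.60 across the sort. ADCY1, FHOD3 and GSTP1 were also more positive across the sort, and IGF2BP1, SERPINB6 and GLDC more positive in H69M. ADCY1 changed by -8.51 in H69M and did not pass the test across the sort (-0.32, adjusted p = 0.0970). IGF2BP1 rose by 7.58 in H69M and changed by only -0.34 across the sort. The change differed in 11026 of 15445 genes. Of 9112 genes called in both comparisons, 2779 were higher in both, 2393 lower in both, 1971 higher in H69M and lower in the PD-L1 high fraction, and 1969 the reverse.

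**Figure D2:**
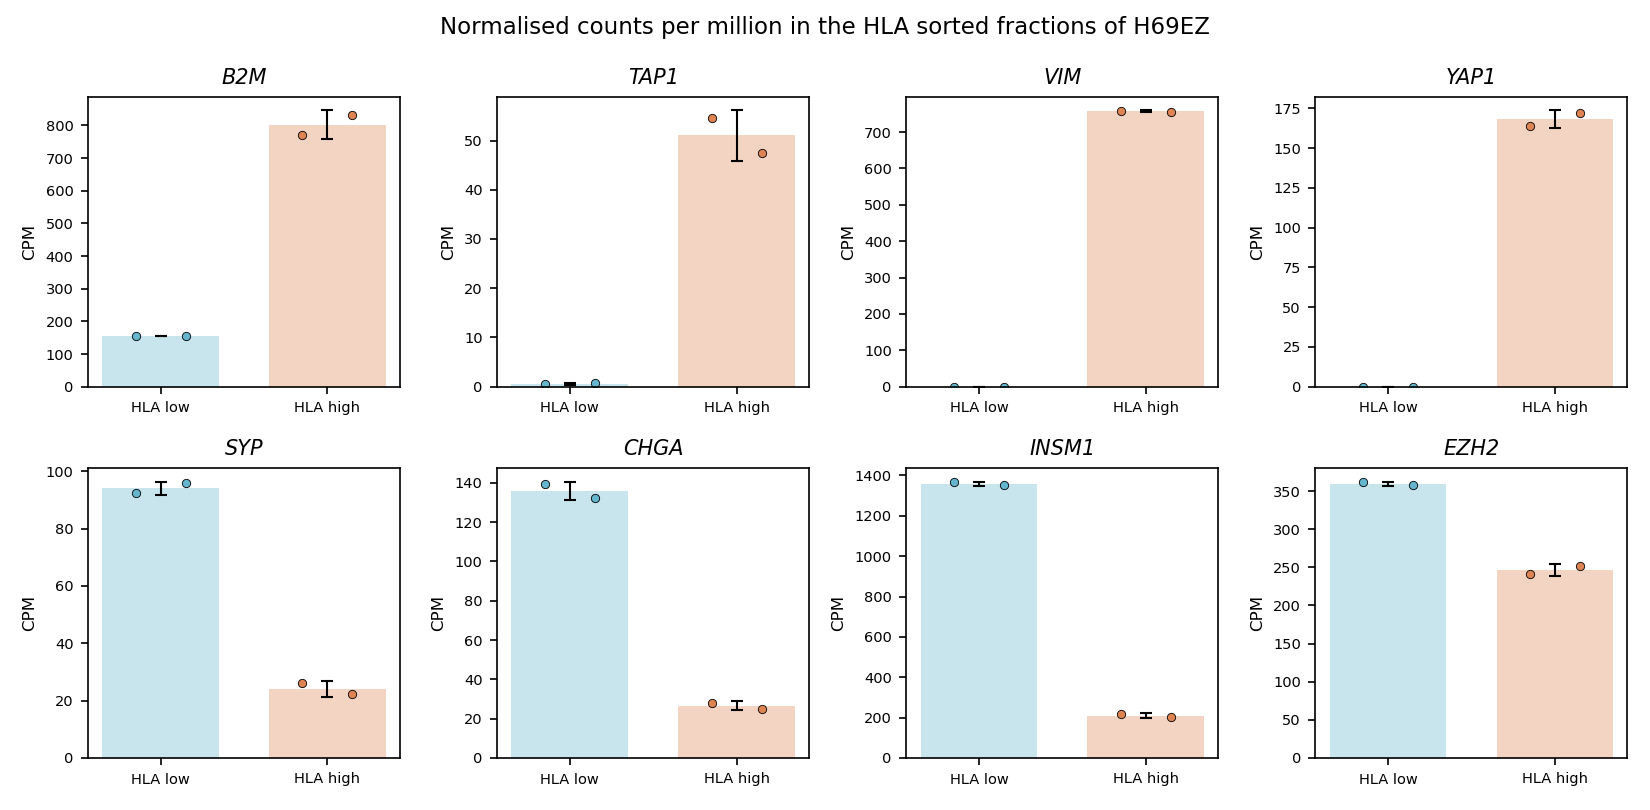
Normalised CPM (vertical axis, linear, from 0) of 8 genes in the HLA low and HLA high fractions of H69EZ. Bars are means, error bars SD and points the 2 libraries of each group. B2M, TAP1, VIM and YAP1 are higher in the HLA high fraction, and SYP, CHGA, INSM1 and EZH2 lower, with EZH2 at 246 ± 7.72 against 360.0 ± 2.65 CPM.

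In H69EZ the HLA high fraction was compared with the HLA low fraction. HLA-B (6.51 ± 0.16) and HLA-C (4.73 ± 0.09) encode sorted proteins and B2M is part of the sorted complex, so they check the sort and are no finding. B2M was at 802 ± 44.4 against 155 ± 0.512 CPM (log2 fold change 2.37 ± 0.06, n = 2 each), TAP1 rose by 6.46 ± 0.13, TAP2 by 3.79 ± 0.09, PSMB8 by 3.67 ± 0.13 and PSMB9 by 8.15 ± 0.25 (8.95 without HLA low replicate 1). NLRC5 rose by 0.54 ± 0.16 (adjusted p = 7.31e-04). CD274 was at 32.8 ± 0.941 against 0.365 ± 0.0413 CPM. INSM1 changed by -2.69 ± 0.06, CHGA by -2.35 ± 0.07, SYP by -1.96 ± 0.07 and EZH2 by -0.55 ± 0.06. VIM was at 757 ± 2.61 against 0.139 ± 6.15e-04 CPM, YAP1 at 168 ± 5.63 against 0.0447 ± 0.0352 CPM and AXL at 224 ± 5.63 against 0.103 ± 0.117 CPM, and REST rose by 6.95 ± 0.14.

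Genes far higher in the HLA high fraction included 2 collagen genes, the transcription factor PRRX1 and the receptor F2RL2. COL3A1, PRRX1 and F2RL2 had no count in the HLA low fraction and were at least 37879-fold, at least 8294-fold and at least 7896-fold higher. COL11A1, with 1 count there, was higher at a ratio of 136692-fold, with a 95% counting interval of 24533 to 5399080.0. Large falls were those of KLF4 (-3.95 ± 0.09), AKNA (-3.88 ± 0.09), NHLH1 (-3.66 ± 0.08) and SULT4A1 (-3.58 ± 0.10). Of the mesenchymal markers 27 of 30 rose and 2 fell (median 6.05), of the non-neuroendocrine signature 25 of 25 rose and 0 fell (6.57), of the YAP and TAZ targets 20 of 22 rose and 2 fell (6.21) and of the integrin and focal adhesion genes 29 of 30 rose and 1 fell (2.75). SPARC rose by 13.47 ± 0.13 (12.83 and 14.97 without 1 of the HLA low libraries in turn), CAV1 by 12.76 ± 0.14 and ITGA5 by 9.45 ± 0.11. Of the MHC class I genes 21 of 22 rose and 0 fell (2.51), in part fixed by the sort, of the interferon-stimulated genes 42 of 44 rose and 1 fell (4.32), and of the TGF-beta and activin targets 17 of 20 rose and 1 fell (1.63). All of these had a camera adjusted p of at most 1.02e-08, and an adjusted p = 0.171 with an estimated correlation. Without the 7 genes of the sorted complex, a list tested after the data were seen, 14 of 15 MHC class I genes rose and 0 fell (median 1.53, adjusted p = 4.54e-07, and adjusted p = 0.171 with an estimated correlation). Fibroblast and stromal markers moved with them (15 of 15 rose and 0 fell, median 6.25, adjusted p = 3.16e-10, and adjusted p = 0.171 with an estimated correlation). So did the endothelial markers (8 of 9 rose and 1 fell, median 6.59, or 4.11 with such genes at their bounds, adjusted p = 0.00949, and adjusted p = 0.20 with an estimated correlation), with the angiopoietin receptor TEK at 231 ± 7.64 against 0.0511 ± 0.0395 CPM.

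Of the NF-kB targets and cytokines 24 of 26 rose and 1 fell in the HLA high fraction, with LIF up by 11.32 ± 0.14 and CCL2 by 4.22 ± 0.07 (adjusted p = 1.20e-10, and adjusted p = 0.20 with an estimated correlation). The receptor tyrosine kinases and ligands had 19 higher, 8 lower and 0 neither, with MET up by 6.79 ± 0.10 (adjusted p = 8.59e-05, and adjusted p = 0.20 with an estimated correlation). The checkpoint and NK cell ligands had 18 higher, 2 lower and 1 neither (adjusted p = 1.34e-04) and the nucleic acid sensing genes 10 higher, 3 lower and 2 neither (adjusted p = 0.0345), each with an adjusted p = 0.217 with an estimated correlation. The neuroendocrine SCLC signature fell (2 higher, 22 lower and 1 neither, median -1.96, adjusted p = 1.97e-11, and adjusted p = 0.20 with an estimated correlation), as did the synaptic and secretory granule genes (3 higher, 18 lower and 4 neither, median -1.15, adjusted p = 1.69e-06, and adjusted p = 0.171 with an estimated correlation). CHGB changed by -2.64 ± 0.07, SYT4 by -2.83 ± 0.07 and ELAVL3 by -2.86 ± 0.07. The lineage and MYC factors had 5 higher, 12 lower and 0 neither (adjusted p = 0.0165, and adjusted p = 0.20 with an estimated correlation), with MYC among those that rose (3.77 ± 0.09). The epithelial markers had 5 higher, 19 lower and 0 neither (adjusted p = 0.00295, and adjusted p = 0.233 with an estimated correlation), with ESRP1 down (-2.89 ± 0.07) and CDH3 up (3.88 ± 0.07). The PRC2 and H3K27 demethylase genes had 1 higher, 8 lower and 4 neither (adjusted p = 0.0486, and adjusted p = 0.346 with an estimated correlation), with the demethylase gene KDM6B down (-1.71 ± 0.08) and EED up (0.66 ± 0.07).

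The H69EZ table also holds the mitochondrially encoded genes. All 13 were lower in the HLA high fraction (median -0.72, adjusted p = 1.01e-04, and adjusted p = 0.335 with an estimated correlation), and they took 4.90% and 5.16% of counts in the HLA low libraries against 2.49% and 2.44% in the HLA high libraries. MT-CO2 was at 2745 ± 37.5 against 7240.2 ± 161 CPM. The sorting stress and immediate early genes had 10 higher, 15 lower and 2 neither and were not called, with EGR1 up by 3.83 ± 0.07 and HSPA1B down (-2.39 ± 0.07). Also not called were the Notch pathway (8 higher, 12 lower and 2 neither), the proliferation genes (6 higher, 10 lower and 10 neither), the cancer testis antigens (3 higher, 2 lower and 3 neither), the MHC class II genes (4 higher, 1 lower and 1 neither) and the leukocyte markers (4 higher, 1 lower and 1 neither). PTPRC, which encodes the leukocyte marker CD45, was at 0.676 ± 0.0349 against 0.0412 ± 0.0255 CPM. Adjusted over the list alone, every list gave the same counts. In all, 12055 of 14819 genes differed, 6098 higher and 5957 lower, 5082 of them at least 2-fold. With 2 libraries a group the spread of a gene was taken wholly from the pool of genes, so many p-values were smaller than could be printed. No list kept its call with an estimated correlation.

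**Figure D3:**
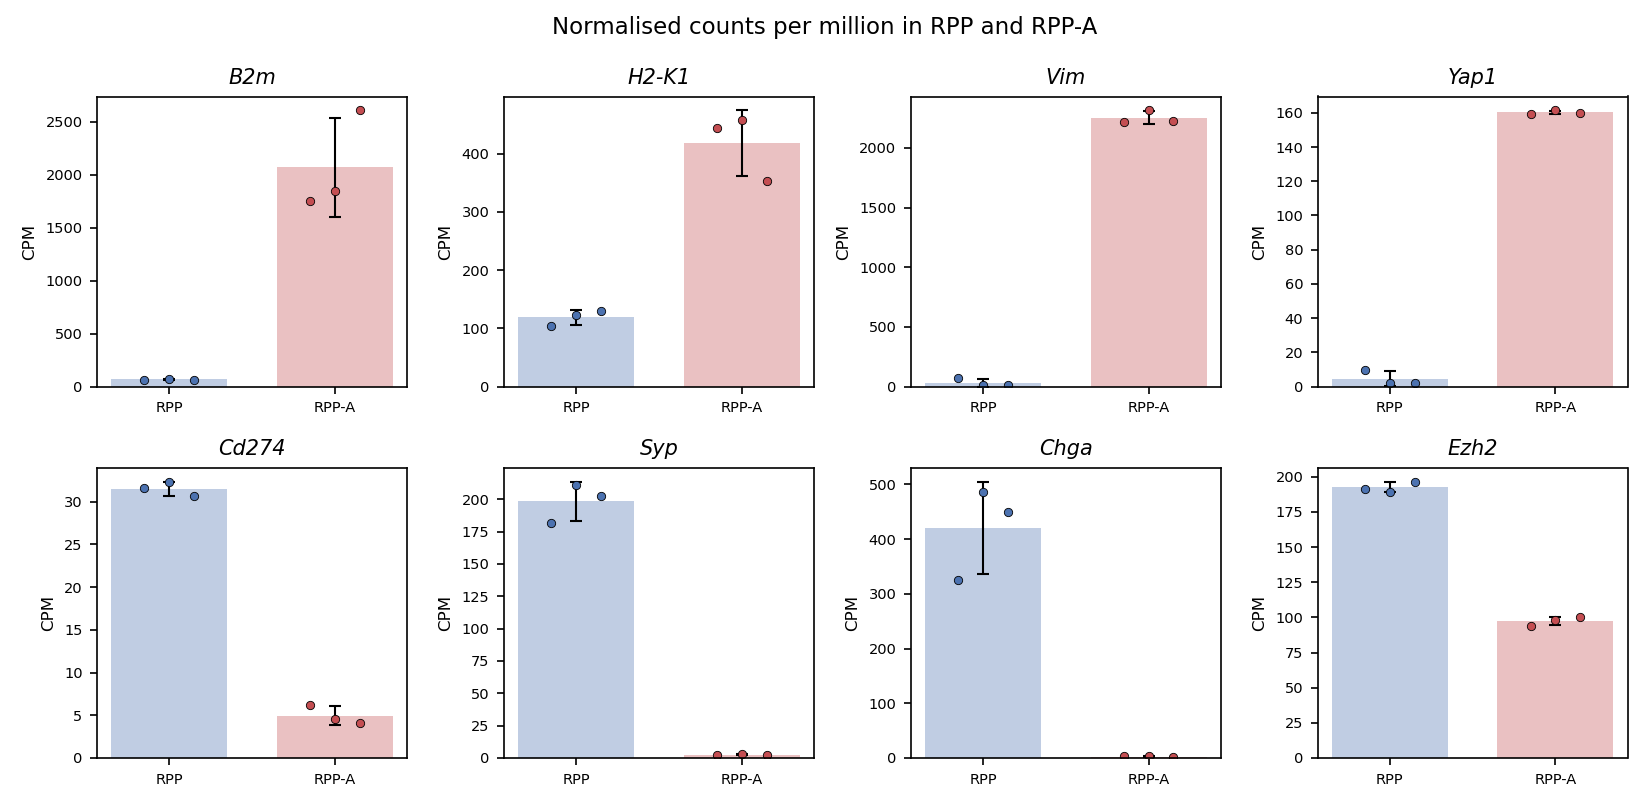
Normalised CPM (vertical axis, linear, from 0) of 8 genes in RPP and RPP-A. Bars are means, error bars SD and points the 3 libraries of each group. B2m, H2-K1, Vim and Yap1 are higher in RPP-A, and Cd274, Syp, Chga and Ezh2 lower, with Cd274 at 4.96 ± 1.07 against 31.5 ± 0.843 CPM.

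In the mouse, RPP-A was compared with RPP. B2m was at 2071 ± 468 against 68.2 ± 4.30 CPM (log2 fold change 4.92 ± 0.20, n = 3 each, adjusted p = 4.91e-07), and the class I heavy chain genes H2-K1 and H2-D1 rose by 1.81 ± 0.14 and 1.66 ± 0.10. Tap1 rose by 2.80 ± 0.14, Tap2 by 2.67 ± 0.22, Psmb8 by 2.55 ± 0.18, Psmb9 by 1.68 ± 0.25 and Nlrc5 by 2.48 ± 0.17. Cd274 was lower in RPP-A (log2 fold change -2.67 ± 0.17, adjusted p = 3.21e-06). Neuroendocrine genes were far lower in RPP-A. Insm1 was at 1.55 ± 0.759 against 298 ± 32.9 CPM and Chga at 2.54 ± 1.06 against 421 ± 84.8 CPM, and Syp changed by -6.33 ± 0.13. Ezh2 changed by -0.98 ± 0.08.

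Of the mouse neuroendocrine SCLC signature all 22 measured genes fell (median -6.95, camera adjusted p = 2.92e-22). So did all 24 epithelial markers (median -7.69, or -7.56 with such genes at their bounds, adjusted p = 4.86e-22), including Krt7 (-6.70 ± 0.16) and Cldn7 (-7.78 ± 0.21), and 28 of 29 synaptic and secretory granule genes, with 1 higher (median -6.60, adjusted p = 1.13e-13). These 3 lists held with an estimated correlation, as did the nucleic acid sensing genes, of which 15 of 18 rose and 2 fell (adjusted p = 9.25e-06). Ddx58, which encodes the RNA sensor RIG-I, rose by 5.48 ± 0.15. The lineage and MYC factors had 3 higher, 12 lower and 1 neither, with Foxa1 (-6.99 ± 0.16), Foxa2 (-7.89 ± 0.27) and Neurod1 (-6.72 ± 0.21) down (adjusted p = 2.38e-04, and adjusted p = 0.175 with an estimated correlation). Large falls were those of Myh14 (-9.18 ± 0.35), Ap1m2 (-9.14 ± 0.17), Arhgef16 (-9.09 ± 0.25) and Cntn3, at 0.0416 ± 0.0721 against 69.8 ± 2.76 CPM, a ratio of 5.94e-04-fold, with a 95% counting interval of 7.19e-05 to 0.00215.

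Steap4, Prelp, Ifi44 and Ms4a4d had no count in RPP and were at least 3513-fold, at least 2827-fold, at least 1769.5-fold and at least 1463-fold higher in RPP-A. Vim was at 2254 ± 52.6 against 33.3 ± 33.0 CPM, Yap1 at 160.2 ± 1.08 against 4.53 ± 4.34 CPM, Axl at 1046 ± 45.1 against 11.3 ± 12.4 CPM and Rest at 80.1 ± 10.05 against 4.04 ± 3.85 CPM. Of the mesenchymal markers 29 of 31 rose and 1 fell (median 5.90, adjusted p = 6.13e-07), of the non-neuroendocrine signature 20 of 22 rose and 2 fell (3.95, adjusted p = 2.33e-04), of the YAP and TAZ targets 19 of 22 rose and 3 fell (3.79, adjusted p = 4.72e-04) and of the TGF-beta and activin targets 17 of 20 rose and 1 fell (2.79, adjusted p = 4.65e-04). Each of these 4 had an adjusted p = 0.324 with an estimated correlation, as had the integrin and focal adhesion genes (19 higher, 5 lower and 3 neither, adjusted p = 0.00647), the NF-kB targets and cytokines (17 higher, 1 lower and 1 neither, adjusted p = 1.39e-04) and the fibroblast and stromal markers (15 higher, 0 lower and 0 neither, adjusted p = 5.30e-05). Cdh11 rose by 6.02 ± 0.19, Timp1 by 7.87 ± 0.30, Tgfbr2 by 3.96 ± 0.11 and Csf1 by 3.43 ± 0.12, while Nt5e fell (-6.07 ± 0.12). Some of these genes were also higher in the library EHK_RPP4 than in the other RPP libraries: Vim was at 71.4 CPM there against 14.2 and 14.2, Yap1 at 9.54 against 2.08 and 1.97, Axl at 25.6 against 3.46 and 4.78 and Rest at 8.48 against 1.73 and 1.90. Without that library the log2 fold change went from 6.09 to 7.35 for Vim, 5.18 to 6.35 for Yap1, 6.55 to 8.03 for Axl, 4.35 to 5.50 for Rest, 7.87 to 8.61 for Timp1, 7.01 to 8.82 for Eng and 6.73 to 7.51 for Cd14. The ribosomal RNA gene Rn45s took 1.63% of the counts of that library, against 0.685% and 0.353% in the others.

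Of the mouse MHC class I genes 19 of 20 rose and 0 fell (median 2.12, adjusted p = 2.35e-06, and adjusted p = 0.217 with an estimated correlation), and of the interferon-stimulated genes 34 of 39 rose and 4 fell (3.68, adjusted p = 1.82e-15, and adjusted p = 0.146 with an estimated correlation). Tapbp rose by 3.22 ± 0.11, Ifit1 by 5.42 ± 0.11 and Gbp2 by 6.08 ± 0.12. The receptor tyrosine kinases and ligands had 19 higher, 7 lower and 2 neither, with Hgf up (5.96 ± 0.17) and Kit and Ret down (-6.70 ± 0.29 and -7.43 ± 0.30; adjusted p = 0.0252, and adjusted p = 0.557 with an estimated correlation). Not called were the checkpoint and NK cell ligands (6 higher, 3 lower and 3 neither), the Notch pathway (6 higher, 11 lower and 3 neither), the PRC2 and H3K27 demethylase genes (2 higher, 8 lower and 3 neither), the proliferation genes (1 higher, 17 lower and 8 neither) and the sorting stress and immediate early genes (15 higher, 3 lower and 8 neither). Endothelial markers were not called either (1 higher, 2 lower and 2 neither, median 0.67 against a mean of -0.39), with Eng up (7.01 ± 0.62) and Vwf down (-4.98 ± 0.19). Of 3 measured leukocyte markers 2 rose, with Cd14 at 32.2 ± 1.90 against 0.307 ± 0.252 CPM. Of 4 MHC class II genes 2 rose, and the 1 measured cancer testis antigen did not pass the test. Adjusted over the list alone, 14 in place of 15 stress genes rose and no other count changed.

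Over all genes, 10975 of 14032 differed between RPP-A and RPP, 5274 higher (48.1%) and 5701 lower, 7016 of them at least 2-fold. The 3 values of the groups were apart in 11545 genes, where chance gives 10%. The split depended on the scaling: with library totals alone, an alternative added after the data were seen, 3962 genes (35.2%) were higher and 7290 lower. With RPPM1 and RPPM2 summed as 1 library 10384 genes differed, and with EHK_RPP4 and RPPM3 left out together 12534 differed.

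**Figure D4:**
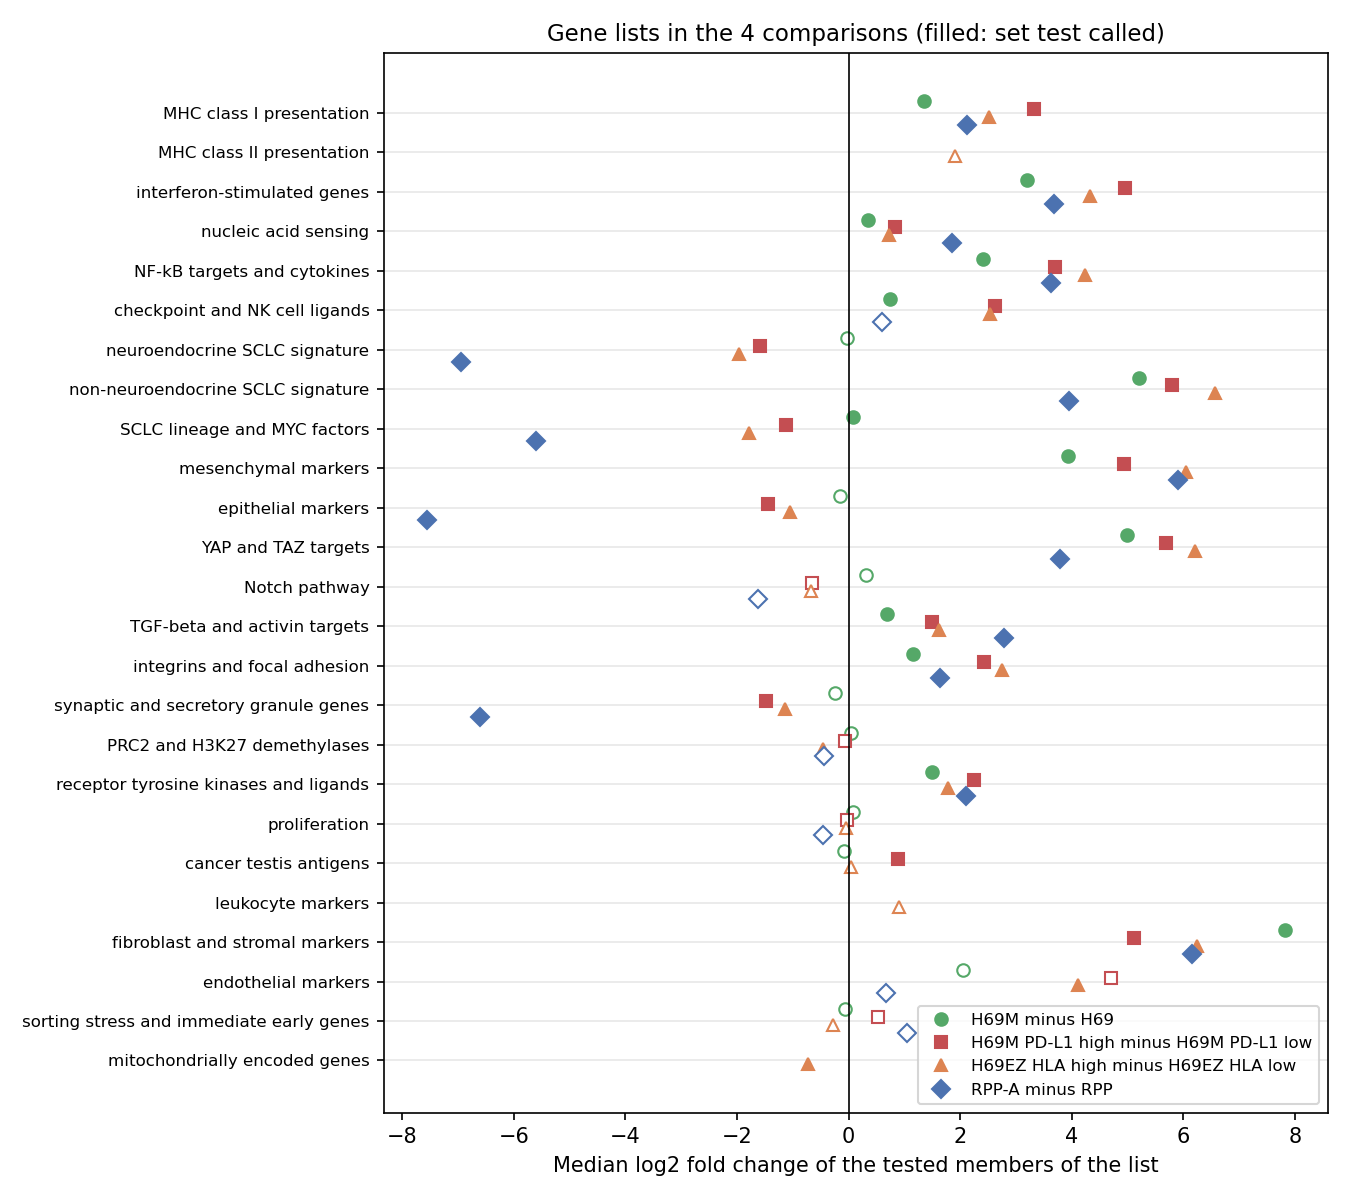
Median log2 fold change (horizontal axis) of the tested members of each gene list (vertical axis) in the 4 comparisons, with members at 0 counts in a group at their bound. Filled symbols mark lists with a camera adjusted p under 0.05. The neuroendocrine signature lies at -1.58, -1.96 and -6.95 in the PD-L1, HLA and mouse comparisons and at -0.02 in H69M against H69.

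The direction of change was then compared between the 4 comparisons, which share no libraries, with mouse genes matched to human genes by symbol. The PD-L1 and HLA sorts were the most alike: of the genes called in both, 79.7% changed the same way, 3835 higher and 3468 lower, where independent lists would share 2323 and 2115. Across genes, which are not independent replicates, the Spearman correlation of their log2 fold changes was 0.625. The PD-L1 sort and the mouse lines shared 67.9% (correlation 0.392), the HLA sort and the mouse lines 63.5% (0.314), and H69M against H69 shared 63.1% with the HLA sort (0.297), 58.0% with the mouse lines (0.181) and 56.8% with the PD-L1 sort (0.215). In all 4 comparisons 1218 of 11213 genes were higher, where independent lists would share 295, and 746 were lower, where they would share 242. The human comparisons all use H69 or cells derived from it, so they are related in origin and the numbers for independent lists are only a reference. At least 2-fold changes in all 4 were seen for 564 higher and 134 lower genes. ACTA2, TAGLN, OAS2, MSRB3 and SAMD9L were among the shared rises. TAGLN, for example, rose by 7.77 in H69M, 7.69 across the PD-L1 sort, 8.40 across the HLA sort and 9.28 in RPP-A. S100A14, CLIC6 and ABCC8 were among the shared falls. S100A14 changed by -4.96, -3.04, -3.89 and -6.06 in the same order.

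**Figure D5:**
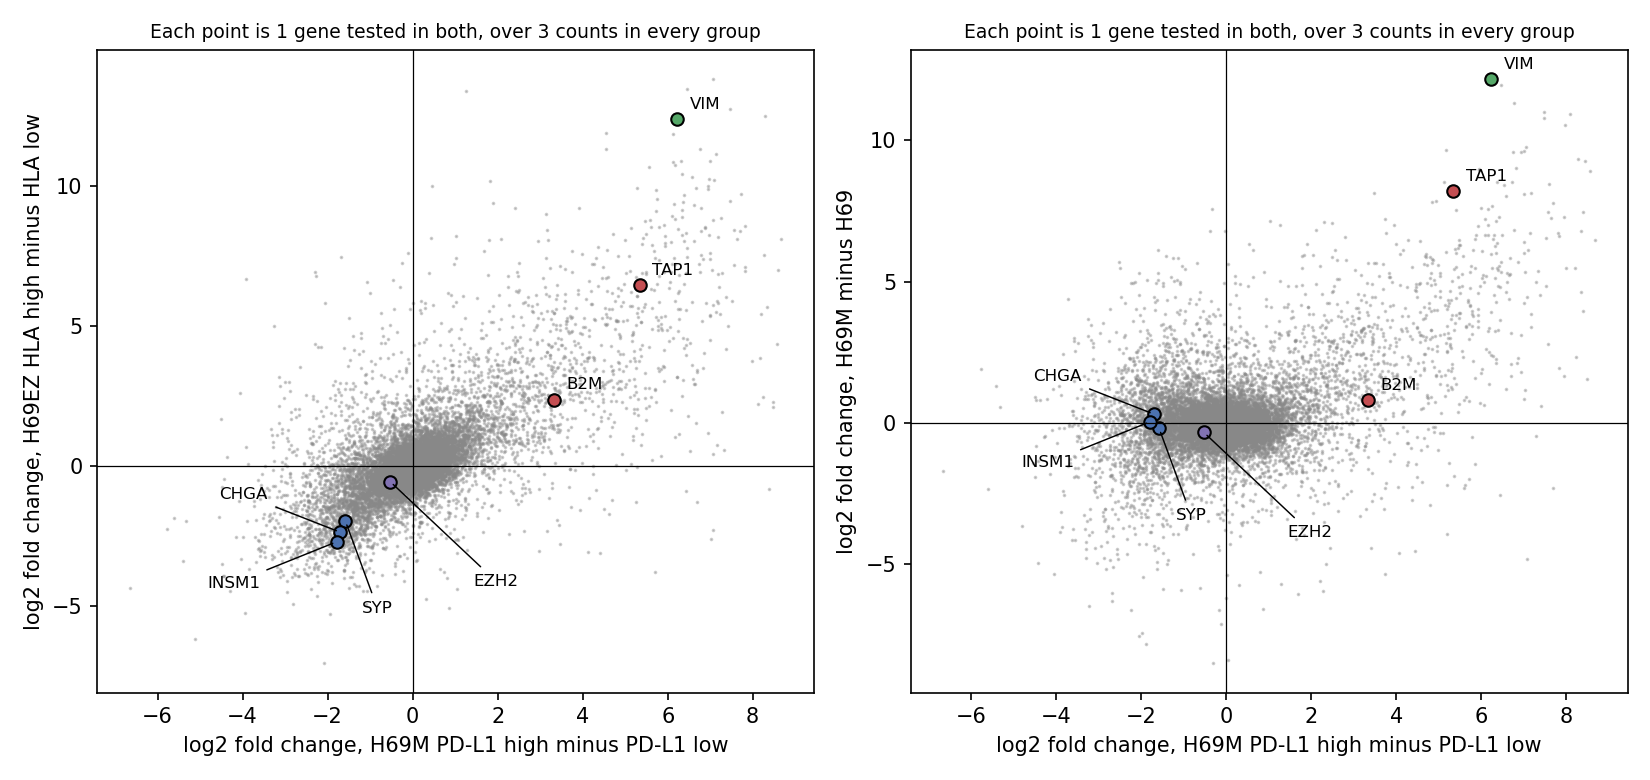
Log2 fold changes of genes tested in both comparisons with over 3 counts in every group: PD-L1 high minus PD-L1 low (horizontal axes) against HLA high minus HLA low (left vertical axis, 13247 genes) and H69M minus H69 (right vertical axis, 14678 genes). Each grey point is a gene, and coloured points are named genes. SYP, CHGA and INSM1 lie below 0 on both axes at the left, whereas CHGA (0.31) lies above 0 on the vertical axis at the right.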

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

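The tests of a mixture, of library size, of carry-over between gates and of RPP-A RNA as the source of genes in EHK_RPP4 were chosen only after the results were seen, except that of 1 common share of RPP-A RNA, and the counts of other splits were planned.

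The change across the PD-L1 sort differed from the change between H69 and H69M in 11026 genes. Sort change minus H69M change was 2.52 for B2M, 0.96 for HLA-B and 1.92 for HLA-C. It was -2.86 for TAP1, -1.33 for TAP2, -2.18 for PSMB8, -1.43 for NLRC5 and -5.93 for VIM (-5.25 and -7.53 without H69 replicate 1 or 2), and -2.01 for CHGA, -1.38 for SYP, -1.83 for INSM1 and -0.19 for EZH2. VIM and TAP1 were near 0 CPM in H69 and higher in the PD-L1 low fraction. Their negative values reflect that lower start, since both were highest in the PD-L1 high fraction. The HLA-B difference was lost without H69 replicate 2 (0.80, adjusted p = 0.0808) and that of EZH2 without H69M replicate 2 (-0.15, adjusted p = 0.0580). The neuroendocrine signature differed with an adjusted p of 9.93e-16. Of 100 splits drawn from 200, 2 gave as many genes, the real one included, a share under 0.05. These splits mix libraries across groups, so their count also follows how far the groups lie apart. They cannot decide whether the 2 changes are equal, and the labels do not say whether replicates were separate cultures. The highest other, 11536, kept both real pairs of groups and swapped the names in 1 pair, and without it the highest was 6528. For the comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05: the real split gave 11196, 12100, 10975 and 11723 genes in H69M minus H69, the PD-L1 sort, RPP-A minus RPP and PD-L1 low minus H69, was the 1 split that gave as many, and the highest other gave 0 in each.

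Some genes moved in opposite ways in different lines, and these differences between lines were not tested. CD274 changed by -2.67 in RPP-A but rose in H69M and the HLA sort. Its rise across the PD-L1 sort was fixed by the gate and is no finding. CHGA changed by -2.35 in the HLA sort and -7.37 in RPP-A, while it rose in H69M.

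Neuroendocrine genes fell across the PD-L1 sort and not from H69 to H69M. If unsorted H69M were a mixture of its sorted fractions in 1 share, all genes would give the same share of PD-L1 high RNA, and the 762 genes at least 8-fold higher in the PD-L1 high fraction gave a median of 0.206 (quartiles 0.143 to 0.257). The 73 genes at least 8-fold lower there, DDIT4, ATF3 and ASNS among them, gave 0.882, a difference of 0.676 that argues against 1 mixture for those genes, but the neuroendocrine signature itself gave 0.410 (quartiles 0.227 to 0.517), a difference of 0.205 with overlapping quartiles, so for the signature a mixture cannot be told apart from a difference in state. The 22 genes of the MHC class I list gave 0.192 (quartiles 0.163 to 0.225), close to the 0.206 above. For that list a mixture is not argued against, so the smaller rise of B2M and HLA-C in unsorted H69M may come from it. Library size is argued against for the neuroendocrine signature, since within groups the signature changed by -0.03 per doubling of library size (95% interval -0.09 to 0.03), which over the whole range of sizes allows at most 0.0922 of the 1.56 between its 2 median log2 fold changes. A difference in state between sorted and unsorted cells stays open and was not tested, as does an effect of sorting itself.

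Genes with at most 3 counts in H69 were seen in the PD-L1 low fraction. A candidate explanation is that PD-L1 high cells carried over into the PD-L1 low gate, which would put these genes at 1 common fraction of their PD-L1 high level, but of the 285 such genes with at least 10 counts in the PD-L1 low fraction only 33.7% lay within 3-fold of their median fraction, and 79, among them SLITRK2, GYG2 and ALOX15, were not lower there than in the PD-L1 high fraction, which argues against carry-over as the source of all. Among the 91 genes with at most 3 counts in H69 that were at 20 CPM or more in the PD-L1 high fraction, a filter that favours carry-over, 81.3% lay within 3-fold of a median of 0.983%, as did 100% of the 5 mesenchymal and YAP and TAZ list members. Of the 91 genes, 11 lay more than 3-fold above that median and 6 more than 3-fold below it, so 1 common fraction did not cover all of them. SERPINB6 reached 18.9% and XAF1 only 0.03%. The median was 0.821%, 0.641% and 1.60% in the 3 PD-L1 low libraries. For those 91 genes carry-over and low expression in PD-L1 low cells themselves both stay open, and the latter was not tested.

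The RPP library EHK_RPP4 stood apart from the other RPP libraries. Of the 367 genes at least 2-fold higher in it than in both others, 77.1% were higher in RPP-A, against 48.3% of all tested genes, which could come from RPP-A cells or RNA but falls short of the 80% set for that reading. Only 59.8% of the 587 genes at least 20-fold higher in RPP-A lay within 3-fold of the median share of 1.79%, so the tests leave open whether RPP-A RNA at 1 share added to some of them. RPP-A is argued against as the source of every such gene, since 24.5% of them (90 genes, among them Rn45s, Jun and Elf3) were at least 2-fold above the RPP-A mean, and as the whole cause, since 61 genes were at least 2-fold lower in EHK_RPP4 than in both others, 20 of them, such as Phgdh and Vwa5a, higher in RPP-A, against 0 such genes in RPP1 and in RPP2. The 0 in RPP1 and in RPP2 is a weak reference, since these libraries lay close together (chi-square per degree of freedom 3.55). Neither could easily be 2-fold lower than both others. The argument rests on the 20 genes themselves, which added RPP-A RNA would raise and not lower. A spread of cell states within RPP was not tested.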

How the results depend on the processing

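The settings with library totals alone, without mitochondrially encoded genes or Rn45s, with RPPM1 and RPPM2 summed, and without EHK_RPP4 and RPPM3 were chosen after seeing the data. With a change of at least 2-fold also required, the genes changed numbered 3669 in H69M minus H69, 5144 in the PD-L1 sort, 3933 in PD-L1 low minus H69, 5082 in the HLA sort, 7016 in RPP-A minus RPP and 5144 in the difference between the PD-L1 sort and H69M minus H69, and 698 genes were shared by all 4 comparisons, since that threshold is stricter. With an estimated correlation 5 lists were called in H69M minus H69, 0 in the HLA sort and 4 in RPP-A minus RPP, against 13, 19 and 15 with the preset one, and fry, which does not compare a list with other genes, called 20 in H69M minus H69 and 25 in the HLA sort. Every other count of changed genes, and of lists called in those comparisons or the PD-L1 sort, stayed within 1.5 times the reported one. In PD-L1 low minus H69 no called list kept its call with an estimated correlation. In the difference only the neuroendocrine SCLC signature, the synaptic and secretory granule genes and the lineage and MYC factors kept theirs. Without 1 library in turn the counts ranged from 10692 to 11255 in H69M minus H69, 11760 to 11946 in the PD-L1 sort, 11262 to 11744 in PD-L1 low minus H69, 10778 to 11283 for the difference, 10644 to 12468 in the HLA sort, where the lone library was assumed to vary like the other group, and 10368 to 11501 in RPP-A minus RPP. With the replicate number as a block the counts were 10915, 11923, 11486, 10791 and 12031 in the same order up to the HLA sort, with 13, 17 and 18 lists called in H69M minus H69, the PD-L1 sort and the HLA sort. In the HLA sort 2 lists lost their call with the block and 1 gained a call. Same-numbered libraries deviated with correlations of -0.16 to 0.09, so the numbers were not read as pairs. For RPP-A minus RPP, no paired analysis was possible because the mouse columns carry no replicate numbers of the labels. The mouse table gave 11006 genes without Rn45s, 10384 with RPPM1 and RPPM2 summed and 12534 without EHK_RPP4 and RPPM3, and the H69EZ table gave 12047 without mitochondrially encoded genes. No gene called in the reported fits was called in the opposite direction in the refits that were run, and no named gene reversed. The difference was not refitted with other filters, with the DESeq2 test, with limma-voom or with only the groups compared. In PD-L1 low minus H69, CD274 lost its call with the block (adjusted p = 0.0517) and EZH2 gained a call with the stricter filter (0.0327) or library totals (0.00469). In the HLA sort CD14 lost its call under 5 settings (adjusted p = 0.0568 to 0.537), and in RPP-A Tek gained a call without EHK_RPP4 (0.00493). The cause of these changes was not tested. Alternatives for normalised values were not run because the tables hold counts. Simulated 1.5-fold changes were called least often in RPP-A minus RPP (44.8%), and whether depth or spread limited it was not tested. With library totals alone the genes higher and lower were 5909 and 5258 in H69M minus H69, 5058 and 7163 in the PD-L1 sort, 6794 and 4909 in PD-L1 low minus H69, 5205 and 7077 in the HLA sort and 4436 and 6711 in the difference, so the balance of directions depends on the scaling.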

Other observations

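The list below was written after the falls of ASNS, ATF3, DDIT4, PCK2 and INHBE across the PD-L1 sort were seen and leaves those genes out, the test over 4 comparisons was set before its result was seen, and the test over the 3 human comparisons, the values of the sorted fractions against unsorted H69M and H69 and the mouse values without EHK_RPP4 were chosen only after.

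A candidate explanation for those falls is a lower amino acid response, the set of genes induced when amino acids are short, in cells with high MHC class I. In a list of 23 such genes, 19 fell and 3 rose across the PD-L1 sort (median -1.33, camera p = 1.38e-11, and 0.00582 with an estimated correlation). In H69M minus H69 19 fell and 1 rose (median -0.57, p = 1.63e-04, and 0.112 with an estimated correlation), and across the HLA sort 18 fell and 4 rose (median -0.66, p = 6.75e-05, and 0.125 with an estimated correlation). At the preset correlation the list was thus lower in 3 of 3 human comparisons. The PD-L1 sort prompted the list, so the fall there is no independent support. The other human comparisons did not stay under 0.05 with an estimated correlation. In RPP-A minus RPP 16 rose and 3 fell (median 1.08, p = 0.0102, and 0.423 with an estimated correlation). The list was lower in 3 of 4 comparisons, the PD-L1 sort that prompted it among them. That met the number set beforehand, but the rise in the mouse lines argues against a fall in all 4. Some of these genes were lower in the library EHK_RPP4 than in the other RPP libraries, and without it 17 rose and 4 fell (median 0.90, p = 0.00426, and 0.0510 with an estimated correlation). Against unsorted H69M, 21 genes were higher and 1 lower in the PD-L1 low fraction (median 1.35, p = 9.07e-42, and 2.56e-04 with an estimated correlation), while the PD-L1 high fraction had 11 higher and 5 lower (median 0.09, p = 0.197). Against H69, which is also labelled MHC class I low, 18 were higher and 2 lower in the PD-L1 low fraction (median 0.94, p = 1.04e-11, and 0.0171 with an estimated correlation), so the list did not follow MHC class I alone. These p-values are not adjusted over lists. A difference in culture or sorting between fractions was not tested.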
